A study of Ovis aries with 18 samples.

How the data were processed

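Small RNA libraries (Illumina TruSeq, per the labels' protocols) were made from ovariectomized ewes (Ovis aries) that received 50 mg of progesterone (P4) daily for 14 days, alone or with 50 mg of RU486 daily from day 8 to day 14. RU486 (mifepristone) is an antagonist of the progesterone receptor. There were 5 ewes per treatment. RNA came from the endometrium (5 libraries per treatment) and from extracellular vesicles (EV) of the uterine lumen (4 libraries per treatment). The labels' protocols state that the uterus was flushed with 10 ml of saline, that the flush passed a 0.22 µm filter, and that vesicles were concentrated by ultrafiltration and isolated by size exclusion. Treatments were given to different ewes, so the libraries of a group come from separate animals.

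The submitters' processing notes name adapter trimming with cutadapt 1.11, the sheep genome build Oar_v3.1 and edgeR (version not given). The aligner, the program that predicted miRNA loci and the filters on reads are not given in the sources used here. Each of 2 deposited tables has a row per miRNA: 495 rows for vesicles and 761 for endometrium, 488 of them in both. Of the vesicle rows, 80 carry a sheep miRNA name, and the others carry the identifier of a predicted locus. Of those others, 319 are listed with a known miRNA of the same seed, the short 5' stretch that selects targets, and 96 are not. A shared seed is not an identity, so such rows are named by their identifier "with the seed of" a miRNA. The deposited tables give no coordinates. The gene table of another sheep assembly (ARS-UI_Ramb_v3.0) was used only to see which miRNA genes neighbour each other.

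The deposited vesicle values are a normalized signal, reads scaled as CPM to an adjusted library size, per the file headers and the values themselves. In each of the 8 columns 100% of values were whole multiples of 1 step (tolerance 0.1 read), so whole reads could be recovered. TMM factors computed from these reads differed from those behind the deposited values by at most 1.98e-06. The recovered reads per library in the table ranged from 97202 to 1062646, and 1 read was worth 1.10 to 10.4 normalized CPM. These are reads assigned to listed rows, so the sequencing depth itself is not known. At 3 reads, the most that a count of 0 allows, the floor was 3.30 to 31.3 normalized CPM, for counting error only. Reads without molecular identifiers are not independent molecules. The vesicle columns name the treatment by its initial letter but not the ewe, so libraries are called P01 to P04 (P4) and R01 to R04 (P4+RU486).

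Both deposited tables also hold the authors' signed fold change and the authors' adjusted p-value (FDR), per the file headers. A fold under 1 is written there as minus its inverse. In the vesicle table a positive fold is higher in P4, as the deposited values show. In the endometrium table the numerator is not named, so folds are given as signed there, with no statement of which treatment was higher. The 10 endometrium columns of values per library have names that match no label and were not used. Therefore no test was run on endometrium libraries, and neither a test of the difference in response between vesicles and tissue nor a comparison of vesicles with tissue was made.

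The design fixed before the data were examined assumed counts and named edgeR's quasi-likelihood test for them. For normalized values, which is what the deposited vesicle values are, it named limma on the log2 scale. The main test was limma (3.58.1, trend, in R 4.3.3) on log2(value + 1), over rows with a mean of at least 10 (229 rows, 99.9% of the reads), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are P4+RU486 minus P4 on that log2(value + 1) scale. It can understate changes of low rows, or overstate them where libraries hold no read. For miR-432 the fitted log2 difference was 2.22 (SE 1.35), or 4.67-fold, where the mean in P4+RU486 was 1.86 times that in P4. Lists of miRNAs fixed beforehand were matched on the name or on the seed name and tested with camera (preset correlation 0.01, lists of at least 3 tested members), with camera at an estimated correlation and with fry. A row matched by seed need not belong to the named family, cluster or region. The lists comprised the let-7, miR-200, miR-29, miR-30 and miR-181 families, and miR-10, miR-99, miR-100 and miR-125 as a list. Clusters were miR-183, miR-17-92 (with its paralogs), miR-23/24/27 and miR-424 with miR-503 (and miR-542 and miR-450). Further lists were the pairs miR-132 with miR-212 and miR-221 with miR-222, the imprinted DLK1-DIO3 region, and miRNAs linked to steroid or hypoxia responses. Lists for other cells were ciliated epithelium, smooth muscle, fibroblast or stroma, endothelium, erythroid, leukocyte, and liver or plasma. Where p-values were adjusted over a list alone, the adjustment covered neither the number of lists nor the alternatives. Shares of reads were compared by 2-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286. Over the authors' folds, a list's median was placed among 10000 random lists of the same size, and its calls were compared with the other rows by Fisher's exact test.

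Named miRNAs were chosen by a rule fixed beforehand: up to 8 past the threshold in each direction, filled to 5 with the smallest unadjusted p, the 10 most abundant rows, and up to 4 abundant members of each list. Other rows are said to have been chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 10, no filter or a mean of 50, median-of-ratios factors, library totals, robust fits, DESeq2 (1.42.0) and edgeR's quasi-likelihood test (4.0.16) on the recovered reads, each library left out in turn, identical rows merged, the 3 shallowest libraries left out, and depth as a covariate. The pseudocount of 10, the mean of 50, the merging, the edgeR tests with its own filter and on the rows of the main test, the removal of 3 libraries and the covariate were chosen after seeing the data. For edgeR with its own filter, the test that the design named for counts, this refers to its use on recovered reads. Of the vesicle rows, 99 have the same values and seed name as another row. Of these, 59 hold at most 3 reads in all, where equal values can arise by chance, and whether such rows share reads was not tested. The rows 10_3805 and X_35741 have equal values in all 8 libraries with 146216 reads in 10_3805, which argues against chance for this pair. Reads counted in both would enter totals and shares more than once. With identical rows merged, the mean total was 431002 in place of 457308 in P4, and 207989 in place of 219882 in P4+RU486.

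On 10 simulated tables with the vesicle libraries' depths and means, limma recovered 6.0% of rows changed by 2-fold and 43.0% of those changed by 4-fold, with 1 wrong call in all. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.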

Results

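MicroRNAs were measured by small RNA sequencing in extracellular vesicles from the uterine lumen and in the endometrium of ovariectomized ewes given P4 or P4+RU486. The comparison asked which miRNAs differed when the progesterone receptor was antagonized during the second week of progesterone treatment. In vesicles, the P4 libraries held 97202, 571791, 1062646 and 97593 reads in listed rows, and the P4+RU486 libraries 244479, 328453, 205410 and 101186. The totals did not differ between treatments beyond their spread (exact permutation p = 0.457). Between 249 and 387 rows had at least 1 read in a library, with means of 317 ± 59.4 (SD, n = 4) in P4 and 295.5 ± 31.8 (SD, n = 4) in P4+RU486 (exact permutation p = 0.543).

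Vesicle RNA of both treatments was dominated by a few miRNAs. The most abundant was miR-10a, encoded within a HOX gene cluster, at 257305 ± 112186 normalized CPM (SD, n = 4) in P4 and 297856 ± 40855 (SD, n = 4) in P4+RU486. It took 25.3% ± 7.23 (SD, n = 4) and 28.9% ± 3.64 (SD, n = 4) of the reads. Next came let-7f, let-7a and miR-26a, a pair of rows with the miR-92a seed and identical values (10_3805 and X_35741), miR-191, miR-148a, miR-30a-5p and 2_16700, which has the miR-27a-3p seed. None of these 10 rows passed the limma test. Among them miR-26a had the smallest unadjusted p, at 73034 ± 18274 (SD, n = 4) in P4 and 51447 ± 12039 (SD, n = 4) in P4+RU486, a log2 difference of -0.50 (SE 0.23, limma adjusted p = 0.334). The 10 most abundant rows together held 67.6% ± 2.89 (SD, n = 4) of the reads in P4 and 70.1% ± 1.61 (SD, n = 4) in P4+RU486, which did not differ beyond the spread (exact permutation p = 0.2).

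**Figure D1:**
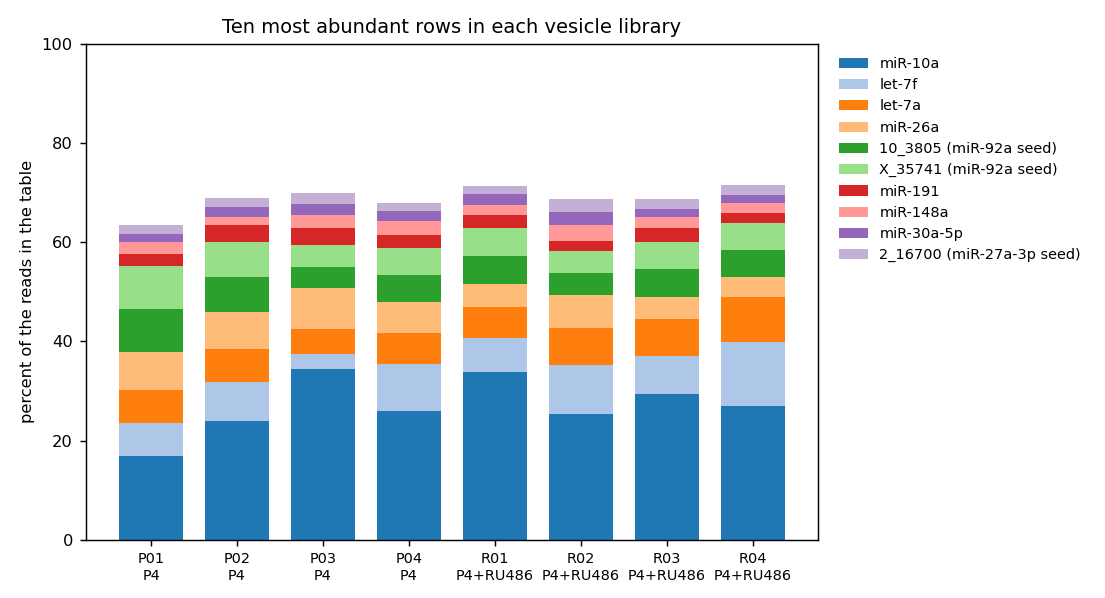
Percent of the reads in the table (y axis, from 0 to 100) taken by the 10 rows with the highest mean, stacked for each of the 8 vesicle libraries (x axis). The bar of miR-10a is the tallest part in every library.

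In vesicles, miR-99a, a member of a family that targets the kinase mTOR, fell with RU486. It averaged 1541 ± 146.2 normalized CPM (SD, n = 4) in P4 and 584 ± 83.9 (SD, n = 4) in P4+RU486. All 4 P4 libraries (1460 to 1760) lay above all 4 P4+RU486 libraries (516 to 695). The log2 fold change was -1.40 (SE 0.25, 95% interval -1.94 to -0.87, limma adjusted p = 0.0225), 2.65-fold lower in P4+RU486. It was the only one of 229 rows past the threshold in this fit, and no row rose in it. DESeq2 called 2 rows higher and 2 lower, edgeR without a filter 3 and 3, and limma with depth as a covariate 4 and 2.

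The 4 other rows with the smallest p among those lower in P4+RU486 did not pass. The row 19_14926, with the seed of miR-885, a miRNA abundant in liver, averaged 284 ± 133.4 (SD, n = 4) in P4 and 71.8 ± 15.5 (SD, n = 4) in P4+RU486, a log2 difference of -1.82 (SE 0.45, limma adjusted p = 0.109). It passed in 4 alternatives (DESeq2, edgeR without a filter, depth as a covariate and without P02). The row X_36488, with the seed of miR-96 of the miR-183 cluster, differed by -1.68 (SE 0.47, limma adjusted p = 0.141), with all 4 P4 libraries above all 4 P4+RU486 libraries. A row with the miR-221 seed, X_36142, differed by -0.72 (SE 0.25) and miR-125b, of the same list as miR-99a, by -0.84 (SE 0.29), both with a limma adjusted p of 0.285. miR-125b was at 4847 ± 1087 (SD, n = 4) in P4 and 2759 ± 819 (SD, n = 4) in P4+RU486.

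The rows with the smallest p among those higher in P4+RU486 did not pass either. The row 20_18845, with the miR-877 seed, averaged 697 ± 149 (SD, n = 4) in P4 and 1639 (libraries from 1165 to 2085, n = 4) in P4+RU486, a log2 difference of 1.23 (SE 0.28, limma adjusted p = 0.109). It also passed in 4 alternatives, with DESeq2, edgeR without a filter, depth as a covariate and without R02. miR-107, encoded in an intron of a pantothenate kinase gene, averaged 1039 ± 124 (SD, n = 4) and 2111 ± 479 (SD, n = 4), 2.03 times as high, with a 95% interval of the log2 difference from 0.45 to 1.56 (limma adjusted p = 0.109). It passed with DESeq2 and with depth as a covariate. Its near-identical relative miR-103, chosen after its values were seen, differed by 0.82 (SE 0.29, limma adjusted p = 0.285). Reads of this pair can be split between them by the counting, and the log2 of their summed values was 0.88 higher in P4+RU486 (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Rows with the seeds of miR-7066-5p (13_7667), miR-149-5p (1_1871) and miR-6529a (1_3033) differed by 1.48, 1.16 and 1.65 (SE 0.41, 0.37 and 0.55). Of these, 13_7667 and 1_3033 passed with edgeR without a filter, and 1_1871 passed in no alternative.

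**Figure D2:**
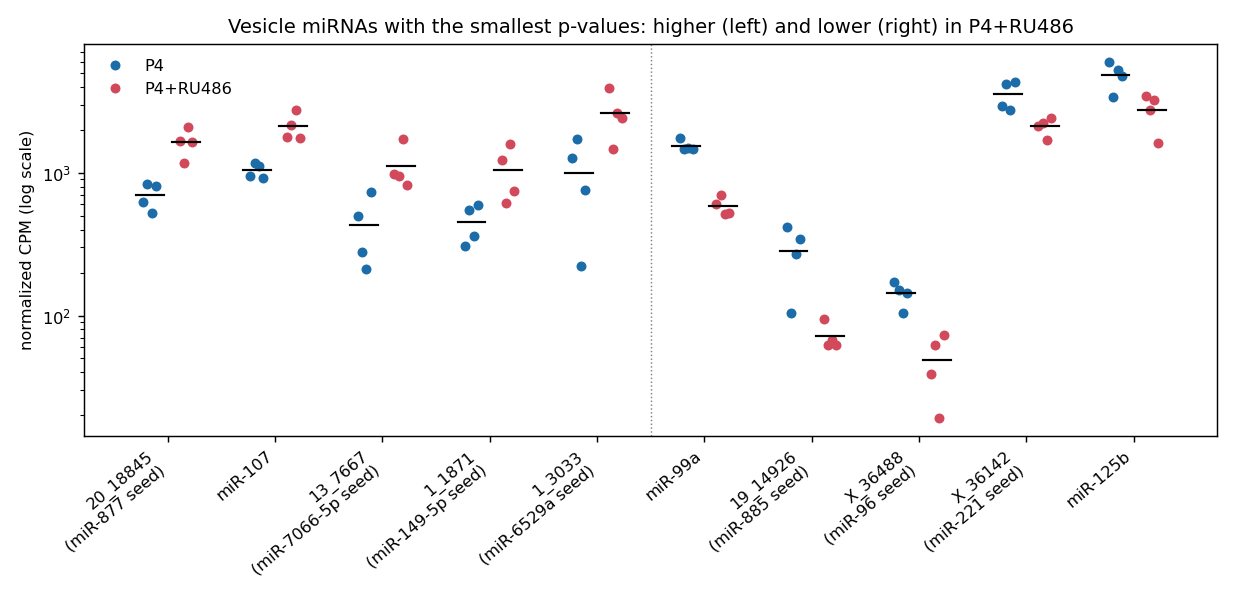
Normalized CPM (log y axis) of the 10 vesicle rows with the smallest p, 5 higher and 5 lower in P4+RU486 (x axis), with a point per library and a line at the mean of 4. For miR-99a the P4 points lie at 1460 to 1760 and the P4+RU486 points at 516 to 695.

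Of the 229 rows, 33 had an unadjusted limma p under 0.05, 17 higher and 16 lower in P4+RU486. In 23 rows (10.0%) the libraries of both treatments did not overlap, where chance gives 2.86%. The call of miR-99a was lost when P04, R01, R03 or R04 was left out, with limma adjusted p-values of 0.0743, 0.0799, 0.0877 and 0.101, and without P01, P04 and R04 together (0.101). The median SE over rows was 0.51 on the log2 scale, and counts of calls on the recovered reads ranged up to 6 rows.

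Among the fixed lists, the let-7 family, which holds back growth genes in differentiated cells, was the only one past the camera test. Its 9 rows had a mean log2 fold change of 0.41 (camera adjusted p = 0.041), 8 of them higher in P4+RU486 (7 under the other scalings) and none past the threshold alone, nor adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.84) and with fry (adjusted p = 0.311), and also without P01 (0.206), P03 (0.159) or R04 (0.558), without the 3 shallowest libraries (0.782), over rows with a mean of at least 50 (0.105) and with median-of-ratios factors (0.0505). let-7f averaged 64613 ± 25866 (SD, n = 4) in P4 and 96804 ± 29438 (SD, n = 4) in P4+RU486, a log2 difference of 0.63 (SE 0.31), and let-7a differed by 0.37 (SE 0.19). A further row with the let-7f seed, 14_9316, differed by 0.82 (SE 0.30). let-7b differed by 0.01 (SE 0.21), with a sign that turned under library totals and under median-of-ratios factors, where 7 of 9 rows were higher. The family took 18.02% ± 4.05 (SD, n = 4) of the reads in P4 and 22.8% ± 4.71 (SD, n = 4) in P4+RU486 (exact permutation p = 0.2).

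The list of miR-10, miR-99, miR-100 and miR-125 held rows with unlike estimates, and a difference between its rows was not tested. Of its 5 rows, 1 passed (miR-99a) and 2 did so adjusted over the list alone (miR-99a and miR-125b), while miR-10a and miR-10b had log2 differences of 0.31 (SE 0.28) and 0.19 (SE 0.63). The row 15_10953, with the same seed as miR-99a, was at 659 ± 256 (SD, n = 4) in P4 and 630 ± 170 (SD, n = 4) in P4+RU486. The mean over the list was -0.35 (camera adjusted p = 0.427), and fry's test for a change in either direction gave an adjusted p of 0.00836. That call was lost under library totals (0.214), without R03 (0.0535) and without the 3 shallowest libraries (0.0567). Adjusted over the list alone, 1 row passed, in place of 2, without P01, P04, R02 or R04 and without the 3 shallowest libraries. Both rows of the miR-221 and miR-222 cluster, which restrains the receptor KIT, passed adjusted over the list alone, with log2 differences of -0.72 for X_36142 and -0.62 for miR-221 (SE 0.25 and 0.26). Adjusted over the list alone, 0 of these 2 rows passed without P04 or R03 and 1 without R02. They held 0.524% ± 0.108 (SD, n = 4) of the reads in P4 and 0.301% ± 0.0292 (SD, n = 4) in P4+RU486, an exact permutation p of 0.0286 and 0.286 after adjustment over 20 lists.

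No row of the epithelial lists passed in the main test. In the miR-200 family, which keeps cells epithelial, 4 of 5 rows were higher and none passed (mean 0.07, camera adjusted p = 0.867). This direction rests on single libraries: 1 of 5 was higher without P01 (mean -0.17), 5 of 5 without P03 (mean 0.29) and 2 of 5 under library totals (mean -0.02). miR-200b was at 5106 ± 4406 (SD, n = 4) and 3025 ± 599 (SD, n = 4). The tested rows of the miR-183 cluster list were matched by seed, so the cluster itself may not encode them all. Of these, 3 of 4 were higher and X_36488, with the miR-96 seed, was lower. X_36488 was the only 1 to pass adjusted over the list alone, though not without the 3 shallowest libraries. The mean of the list was 0.02, from -0.09 to 0.15 with 1 library left out, and below 0 under both other scalings, while its median was 0.58. Of the 3 higher rows 2 have identical values, and with identical rows merged 2 of 3 were higher, the mean was -0.18 and the camera test turned downward (no call). For ciliated epithelium, the 3 rows of miR-34 seeds had a mean of 0.14 (camera adjusted p = 0.867). Adjusted over the list alone, 1 of them passed without P01, and 2 of 4 without the 3 shallowest libraries. The most abundant, 15_10278, was at 8596 ± 2742 (SD, n = 4) in P4 and 10481 ± 3629 (SD, n = 4) in P4+RU486.

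Shares of the lists for other cells were not all below those of the epithelial lists. Smooth muscle rows held 1.34% ± 0.295 (SD, n = 4) of the reads in P4 and 1.19% ± 0.195 (SD, n = 4) in P4+RU486. The miR-200 family held 1.51% ± 0.741 (SD, n = 4) and 1.30% ± 0.235 (SD, n = 4). The leukocyte, erythroid, stromal and liver or plasma lists had lower mean shares than these. The leukocyte rows (miR-150 and the seeds of miR-342 and miR-155) were all lower in P4+RU486, with a mean of -0.57 (-0.31 without P01) and none past the threshold (camera adjusted p = 0.427). Among the alternatives, edgeR without a filter called miR-150. Without the 3 shallowest libraries 1 of the 3 was higher. The list also names miR-142, but its matching rule left out 11_5329, with the miR-142b seed. That row went the other way, higher in P4+RU486 by 2.28 (SE 1.03, limma adjusted p = 0.334), with a median of 8 reads per library. miR-150, a lymphocyte miRNA, was at 5859 ± 5314 (SD, n = 4) and 2282 ± 1367 (SD, n = 4), and the P4 mean included 13655 in P01, the library farthest from the others on the first principal component. The erythroid row 26_23579, with the miR-486 seed, was at 2862 ± 3343 (SD, n = 4) in P4 and 3189 ± 1695 (SD, n = 4) in P4+RU486. It differed by 1.18 (SE 0.90), by 0.43 without P02, by 2.02 without P04, and by 3.38 (limma adjusted p = 0.042) without the 3 shallowest libraries. The stromal miR-199a-3p differed by -0.03 (SE 0.68), by -0.59 to 0.65 with 1 library left out, and was at 849 in P01, against a median of 168 in the other libraries. Of the smooth muscle rows, miR-143 differed by -0.08 (SE 0.22) and 5_29566, with the miR-145 seed, by -1.43 (SE 0.59, limma adjusted p = 0.317). In the liver or plasma list, 19_14926 passed adjusted over the list alone, though not without the 3 shallowest libraries, and miR-194 differed by 0.14 (SE 0.49). Their share was 0.0362% ± 0.0183 (SD, n = 4) in P4 and 0.0121% ± 0.00154 (SD, n = 4) in P4+RU486 (exact permutation p = 0.0286, 0.286 after adjustment). No row matched the endothelial list.

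No row of the remaining lists passed, and their camera adjusted p-values lay between 0.427 and 0.867. In the miR-17-92 and paralogous clusters 4 of 8 rows were higher (3 to 4 with 1 library left out), and among the miRNAs linked to steroid or hypoxia responses 5 of 6 (4 to 5). In the miR-29 family 1 of 4 was higher (0 to 1), with a mean of -0.46 that stayed below 0 with 1 library left out (-0.79 to -0.27). Its rows 12_6721 and 12_6717 have identical values, so 1 signal may weigh double in that mean. The same limit applies to 10_3805 and X_35741 in the miR-17-92 list. In the miR-30 family 3 of 7 rows were higher, and from 1 (without P01) to 4 with 1 library left out, with a mean below 0 each time (-0.20 to -0.05). In the miR-181 family 1 of 3 was higher, and 2 without P01, P02 or R01. In the list of the miR-424 and miR-503 cluster 2 of 4 were higher, with a mean of 0.40 that ranged from 0.00 to 0.72 with 1 library left out. These 4 rows have the seeds of miR-450a, miR-450b and miR-542-3p, and none is listed with that of miR-424 or miR-503. Since a row can be listed under another miRNA of the same seed, this does not show that miR-424 and miR-503 are absent. X_35722, with the miR-16b seed, is numbered close to these rows and was chosen after its values were seen. It differed by -1.54 (SE 0.61, limma adjusted p = 0.299), and whether it belongs to the cluster was not tested. X_35725, with the miR-542-3p seed, differed by 1.27 (SE 1.46) at a mean of 10.5 normalized CPM. In the miR-23/24/27 clusters 2 of 6 rows were higher (mean -0.06), and 6 of 6 without P03 (mean 0.15). Of these, 5_28971 and 2_16698 have the same mean value and may hold 1 signal. In the DLK1-DIO3 list, whose most abundant row, 3_25383, was matched by seed alone, 2 of 6 were higher, with a mean of 0.04. That mean was 0.83 without P01 (3 of 4 higher), -0.37 without P02, -0.48 without P03 and -0.05 under library totals. Without a filter 24 of 33 DLK1-DIO3 rows were lower (mean -0.42, camera adjusted p = 0.14, from 0.0200 unadjusted), so the list has no settled direction here. No row of the miR-132 and miR-212 cluster reached the mean of 10. miR-30d, at 20812 ± 3836 (SD, n = 4) and 14305 ± 1840 (SD, n = 4), had a log2 difference of -0.53 (SE 0.21, limma adjusted p = 0.285). miR-25 differed by -0.31 (SE 0.19), and miR-21 by 0.10 (SE 0.29).

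**Figure D3:**
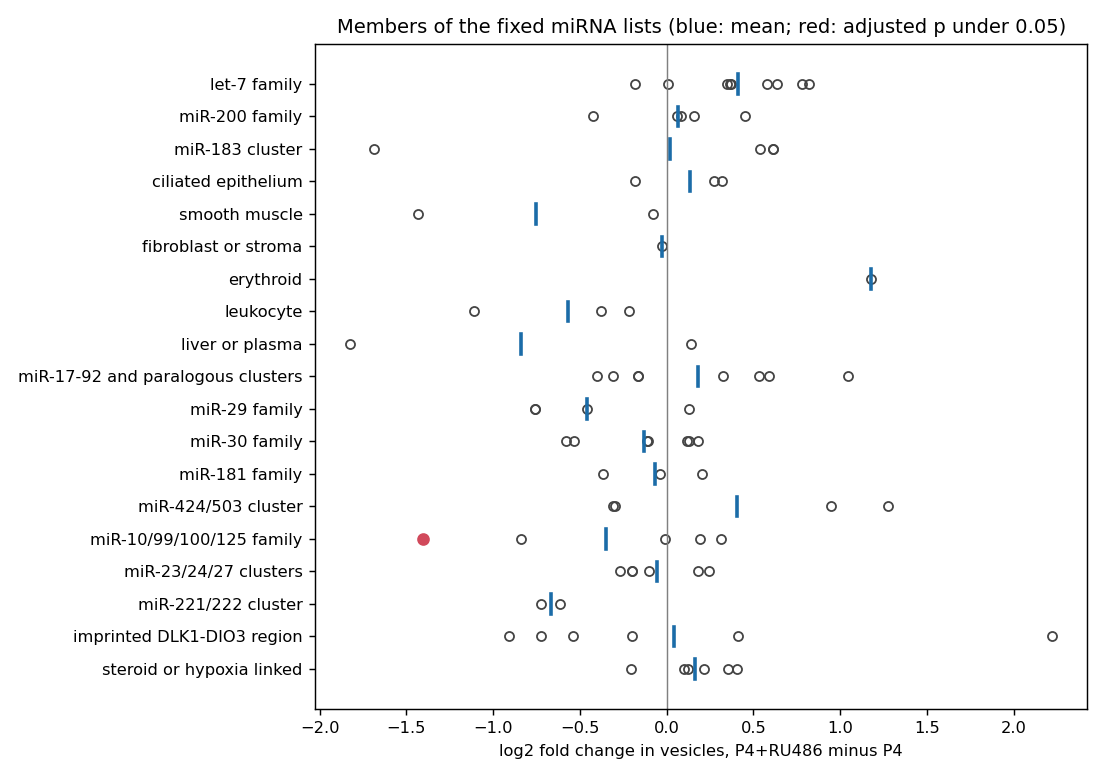
Log2 fold change in vesicles, P4+RU486 minus P4 (x axis), of each tested row (circle) in the fixed lists (y axis), with a blue line at the list's mean and a red point where the adjusted p is under 0.05. miR-99a, at -1.40, is the only red point, and 8 of the 9 let-7 rows lie above 0 (7 under the other scalings).

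In the authors' deposited table for vesicles, 9 rows had an adjusted p under 0.05, all with few reads. Positive there (higher in P4) were 19_14302 and 3_25056 with the miR-135a seed (folds 3.39 and 3.61), 11_5450 and 24_21621 with the miR-365-3p seed and identical values (fold 3.17), X_35722 with the miR-16b seed (2.19) and 24_21619 with the miR-193a-3p seed (3.1). Negative in the authors' deposited table were 11_5329 with the miR-142b seed (fold -3.69, adjusted p = 1.36e-05), 1_1746 with the miR-6980-5p seed (-2.83) and 23_21291 with the miR-7687-3p seed (-3.72). These 9 rows had the same direction in the limma test, where their adjusted p-values were 0.285 to 0.631. For miR-99a the authors' deposited table gives a fold of 2.64 with an adjusted p of 0.81, so no row was called in both.

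In the endometrium, the authors' deposited table held 9 rows with an adjusted p under 0.05 for the same treatments. The numerator of these folds is not named, so their sign is given as coded. The most extreme adjusted p was that of 16_11384, with the seed of miR-34b, a miRNA of multiciliated cells, at a fold of 8.10 (adjusted p = 3.6e-06 in the authors' deposited table). Also positive in the authors' deposited table were miR-431 (4.86), miR-665-5p (3.18) and miR-665-3p (1.62), which the imprinted DLK1-DIO3 region encodes, and the rows 14_9523 with the miR-7018-3p seed (4.97), 5_29555 with the miR-2312 seed (2.61) and 19_14926 with the miR-885 seed (2.10). Negative were miR-10b (-1.13, adjusted p = 0.00114) and 3_26521 with the miR-7864 seed (-5.36, adjusted p = 0.00686). The next negative rows, miR-26a (-1.14), 10_3799 with the miR-19a seed (-1.47) and 19_14780 with the miR-3926 seed (-4.11), had an adjusted p of 0.096 in the authors' deposited table and did not pass.

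By list, the authors' deposited table for endometrium gave these counts. In the DLK1-DIO3 region 3 rows were called, with 40 positive and 66 negative folds, which was no more calls than in other rows beyond chance (Fisher's exact p = 0.118, adjusted p = 0.588). All 9 let-7 rows were negative, for example let-7f at -1.43, and none was called. Their median signed log2 fold of -0.40 lay at percentile 3.25 of 10000 random lists. The 6 rows matched to the miR-183 cluster lay at percentile 1.95, with 4 negative and none called. These negative rows form pairs with the same fold and adjusted p. JH923873.1_37347 and JH923873.1_37351 were at -1.82, and JH923873.1_37345 and JH923873.1_37349 at -1.49. Each pair may be 1 signal counted in both rows, so this percentile may be too extreme. Ciliated epithelium lay at percentile 98.3, with 3 of 4 rows positive and 1 called (Fisher's exact adjusted p = 0.386). In the miR-23/24/27 clusters all 7 rows were negative, and in the miR-181 family all 4, without a call. These counts also include rows with equal folds: 5_28971 and 2_16698 (-1.3) in the former, miR-181a and miR-181a-1 (-1.34) in the latter. miR-99a had a fold of -1.04 and an adjusted p of 0.985 in the authors' deposited table for endometrium. Members of one list are not independent, so the percentiles describe these tables only.

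The authors' folds of the 2 tables were set side by side over 488 rows listed in both. Spearman's rho across rows was -0.02 and Pearson's r 0.01 (permutation p = 0.716 for rho), and 50.2% of rows had the same sign. Rows are not independent replicates, and no row was called in both of the authors' deposited tables. Over the 124 rows with a vesicle mean of at least 100, rho was 0.04 (permutation p = 0.663). The sign of the endometrium folds is not named, and a relation turned round would have shown as a negative rho of the same size. Whether the response differed between vesicles and endometrium was not tested.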

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

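The counts of splits, depth as a covariate and the tests of the same-seed row, normalization, few reads and other cells, and the range over libraries used for shallow sequencing, were chosen only after the results were seen. Over the reported rows and shares, 12 groups of 4 libraries had a library far from the other 3. Chance gives about 1 in 20, or 7.30 here. In P4, P01 had the highest miR-99a at 1760 (others 1460 to 1486) and the highest miR-432 at 47.1 (others 0 to 2.20). P02 had the lowest value of 12_6721 and of its identical copy 12_6717, with the miR-29b seed, at 71.1 each (others 105 to 111). P03 had the highest miR-23a at 2526 (others 833 to 970). In P4+RU486, R01 had the highest 19_14926 at 94.9 (others 62.6 to 66.9). R02 had the highest miR-148a at 31382 (others 21977 to 22724), 3_27218 with the miR-200a seed at 4524 (others 2008 to 2433) and miR-150 at 4318 (others 1462 to 1837). R03 had the highest miR-199a-3p at 579 (others 135.7 to 194.1) and miR-432 at 62.2 (others 6.26 to 12.9), and R04 the lowest miR-23b at 491 (others 722 to 759).

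The fall of miR-99a was the only call of the limma test. Of the 35 ways to split the 8 libraries into 4 and 4, 3 gave at least 1 call, the real one included, and the highest other gave 3, so chance is not excluded for a count of 1. For the 33 rows with an unadjusted p under 0.05 only the real split, 1 of 35, gave as many, and the highest other gave 28. That other split parts the 4 shallowest libraries from the 4 deepest, and whether depth lay behind its count was not tested. A difference in depth is argued against for miR-99a, whose log2 fold change with log2 depth as a covariate was -1.40 (SE 0.21). Reads shifted to the row of the same seed are argued against too, since 15_10953 changed by -28.4 normalized CPM (SE 153.6) where miR-99a lost 957. The treatment itself remains open as a hypothesis.

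The authors' 9 vesicle calls were not called by limma, nor by DESeq2 or edgeR under any setting that tested them. Normalization is argued against, because the recomputed scaling factors differed from the deposited ones by at most 1.98e-06. Few reads may be part of it: the median of the called rows was 4.5 reads per library, against a lower quartile of 5.5 over tested rows. Replicates no more variable than counting noise are argued against, since the called rows' within-group variance was 3.16 times that of Poisson counts, at percentile 92.1 of random sets of 9 rows with similar reads. How the authors' test estimated the spread is not given in the sources used here and stays open.

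Library P01 lay farthest from the others on the first principal component (26.4% of the variance), at -16.7 against -5.41 to 10.6, though the gap to the nearest library was only 0.414 of the range. Shallow sequencing cannot be told apart: with every library thinned to 97202 reads, the median correlation of P01 minus the next lowest was -0.00756 on average (P01 lowest in 18 of 20 thinnings). For correlations averaged over the thinnings first, the gap from P01 to the next library was 0.444 of the range over libraries. The bound set beforehand, the SD over thinnings (0.00746), was narrowly passed, which by that rule alone would argue against shallow sequencing. That bound holds counting noise only and was judged, after the result, too narrow for a difference between libraries. P04 and R04, about as shallow, lay at 3.13 and -3.23. A candidate explanation is more RNA from blood, immune or stromal cells and less from epithelium: the median log2 ratio of 5 such rows to the other libraries exceeded that of 12 epithelial rows by 1.62 (exact permutation p = 0.0983 over rows). That difference was 1.03 in P04 and -1.42 in P03, so it is not particular to P01, and miR-150 (7.43 times the median of the others) and miR-199a-3p (5.02 times) rose where the miR-155 seed row was 1.114 times and 15_10275, on the ciliated list, 2.05 times, so few rows that go both ways keep this open.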

How the results depend on the processing

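The direction of miR-99a held in all 24 alternatives, with log2 fold changes of -1.49 to -1.29, and it passed in 19 of them (adjusted p over all 24 from 1.27e-06 to 0.101). Against 1 called row, edgeR without a filter gave 6, DESeq2 gave 4 and the fit with depth as a covariate gave 6. Leaving out 1 library gave 0 to 2, 2 without P02 or R02. The cause was not tested. Over 68 named rows and 1604 values, 14 passed that did not before, 5 no longer passed (all miR-99a) and none reversed past the threshold, while 81 changed sign without a call. Against 1 called list, 0 were called with an estimated correlation, with fry's directional test, at a mean of 50, with median-of-ratios factors (let-7 at 0.0505) and without the 3 shallowest libraries, and 0 to 1 with 1 library left out. By fry's test in either direction the miR-10, miR-99, miR-100 and miR-125 list passed, and the miR-17-92 list did so only without P03 (adjusted p = 0.00187). The cause was not tested, apart from fewer rows or libraries in some. Adjusted over the list alone, rows passed in lists without such a call before: 1 each of miR-30 under library totals, miR-424 with miR-503 without P02, leukocyte without P03, smooth muscle without P04 or R03, ciliated epithelium without P01 (2 without the 3 shallowest), and erythroid without P04 or without the 3 shallowest. The erythroid list has 1 row, so this adjustment leaves its p unchanged. The share of the 10 most abundant rows, the totals and the rows detected had no call under any alternative run. With 1 library left out, the exact permutation test cannot reach 0.05, so those alternatives could give no call and do not test robustness. Median log2 fold changes over all rows were 0.04, 0.00 and -0.06 under the 3 scalings. No paired analysis was possible because the vesicle columns carry no ewe number and the endometrium columns were not used. For the same reason no alternative was run for the endometrium (9 rows in the authors' table), for the difference between vesicles and tissue, or for both in 1 model. Depth limits low rows most: 1 read in R04 was worth 10.4 normalized CPM, so a row at the mean of 10 rests on about 1 read there.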

Other observations

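The tests in this part were chosen only after the results were seen. miR-99a is encoded next to let-7c, as the neighbouring genes of the sheep reference table (ARS-UI_Ramb_v3.0) also show. A hypothesis was that the products of these neighbouring genes fall together in the vesicles, which was examined for let-7c only. let-7c was at 5733 ± 666 (SD, n = 4) in P4 and 5182 ± 1413 (SD, n = 4) in P4+RU486, a log2 fold change of -0.18 (SE 0.25), which argues against a joint fall of the size of miR-99a. Reads of let-7c can be shared with other let-7 members, which limits this comparison. miR-125b differed by -0.84 (SE 0.29), in the direction of miR-99a. In that sheep reference, the nearest miRNA genes listed around that of miR-99a are MIR30C, MIRLET7C and MIR16B, none named for miR-125b. Genes farther away were not examined, and a gene that the reference does not annotate would be missed.

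Both rows with the let-7f seed and a locus identifier had the smallest unadjusted p of the let-7 list. X_35370 was at 1303 ± 470 (SD, n = 4) in P4 and 2120 ± 123 (SD, n = 4) in P4+RU486, with no overlap between treatments and a log2 difference of 0.78 (SE 0.30, limma adjusted p = 0.285), close to that of 14_9316. With depth as a covariate, miR-103 and miR-107 both passed, at 0.94 (SE 0.18) and 1.05 (SE 0.21) with limma adjusted p-values of 0.0346 and 0.0376. In the authors' deposited table for endometrium, miR-103 had a fold of -1.03 and miR-107 a fold of 1.03, neither called.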
